A study of Sus scrofa with 29 samples.

How the data were processed

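MicroRNA (miRNA) abundance was measured in pig conceptuses (the embryo with its membranes) and trophoblast (the outer layer that attaches to the uterus) from Hampshire x Duroc gilts on days 10 (D10), 11 (D11), 12 (D12), 16 (D16) and 20 (D20) of pregnancy. Per the labels, RNA was extracted with a miRVana kit, 100 ng of total RNA was labelled with Cy3, and the samples were hybridised to Agilent 1-colour miRNA arrays. The 29 arrays were the samples and lay on 5 slides. Each deposited scanner file gives 13315 spots, of which 12600 were non-control spots, 434 negative controls and 281 positive controls. The spots belonged to 1635 probes, with 5 to 20 spots each, for 630 named miRNAs. Of these names, 235 were pig (ssc), 373 human (hsa), 13 mouse (mmu) and 9 cattle (bta). No genome came with the series, so no positions are given and the names are those of the array design. Probes of near-identical family members, such as those of let-7, miR-302 or miR-199, can bind each other's targets.

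Per the file headers, the deposited scanner files were made by Agilent Feature Extraction 10.7.3.1, which the labels give as 10.7, and hold spot intensity after spatially detrended background subtraction. The file headers name no normalization between arrays, and negative intensity values occur. The deposited processed table holds log2 values that the authors had normalised between arrays. It covers 3709 of the non-control spots, from 230 miRNAs, and includes all 218 miRNAs tested here. The labels name limma among the tools but not the steps. Over spots with an intensity above 100, each column of that table correlated with log2 of the same array's processed intensity with r of at least 0.99988 across spots, which are not independent replicates, and slopes of 0.9799 to 0.9982. The column medians lay between 4.944 and 5.369. Whether these values were centred or scaled beyond an offset per array, and how spots near background were treated, stays unknown, so they served as an alternative and the scanner intensities as the main source.

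Each array was scaled by the 75th percentile of its processed intensity over the 90 probes that the scanner software called well above background on all arrays. Spots of a probe were averaged on the log2 scale. Values below the 1st percentile of scaled signals that were well above background were set to that floor, -6.853 on the log2 scale. A probe counted as detected on an array when at least 0.5 of its spots were well above background. For the 628 miRNAs with several probes, up to 4 each, the probe with the highest mean over all arrays was kept. The values of a miRNA come from this probe. Where arrays are counted on which a miRNA was detected or above background, any of its probes counts. A miRNA was tested when its kept probe was detected on at least 80% of the arrays of at least 1 day (4 of 5, or 8 of 9). This left 218 miRNAs, 129 with pig names and 89 with names of other species. For 55 of them the kept probe was detected on every array, and these are called detected on every array below. For arrays, the number of samples limits the precision.

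Differences between days were tested with limma 3.58.1 under R 4.3.3 (tables were read with version 1.17.8 of data.table). One model gave each day a mean over all 29 arrays, and variances were moderated with a trend on abundance (3.55 prior degrees of freedom). A moderated F test over the 5 days and 5 pairs of days (D11 against D10, D12 against D11, D12 against D10, D16 against D12, and D20 against D16) were read at a Benjamini-Hochberg adjusted p of 0.05 within each comparison. Values are log2 differences ± the standard error (SE) of the model. A miRNA below background on all arrays of 1 day is given only as a fold of at least a bound, computed against the lowest signal called well above background on each of those arrays, or with no fold where that bound was under 1. Fixed miRNA lists with at least 3 measured members were tested with camera, at a preset correlation between miRNAs of 0.01, with adjustment over all lists and pairs. The same lists were tested with an estimated correlation and with fry, which tests a list against no change rather than against the other miRNAs. List medians are given also with members below background set at their bound, or at 0 where no bound could be had.

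The miRNAs named were chosen by rule. In each pair these are the 8 highest and 8 lowest log2 differences among miRNAs past the test, the 3 members with the smallest p of each list that had a member past it, and the 4 smallest p where fewer than 4 passed. For the F test these are the 5 smallest p. The 24 lists cover pluripotency clusters, miR-17 to miR-92 clusters, let-7, miR-99 and miR-125, miR-200, miR-183, mesenchymal, endothelial, erythroid, leukocyte, striated muscle, neural, liver, HOX, DLK1-DIO3, the primate chromosome 19 cluster, the X-linked miR-424 cluster, miR-34 and miR-449, miR-15 and miR-16, miR-23, miR-24 and miR-27, miR-26, miR-29, miR-30, and hypoxia. The lists, the rule, the main tests and the alternatives were fixed before the data were examined, except for the alternatives without the dim D10 arrays and without D20. Tests of scaling, brightness and blood cells on D20, and the divisions within slides, were also chosen after results were seen. Detected miRNAs per array were compared with a two-sided permutation test of 100000 resamples.

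Each alternative was run on its own against the main analysis. The scaling was replaced by the percentile over all probes, by quantile normalization, by normexp background correction with an offset of 50, or by the authors' values. Normexp was planned on mean spot signals, but the files hold only median signals, which were used. Normexp thus changed the spot signal, the background and the offset together, and the authors' values differ by steps that are not known, so both differ by more than the scaling under which they are counted. Other alternatives were no filter on dim probes, only miRNAs detected on every array, no floor, the mean of all probes of a miRNA, the scanner software's total gene signal, pig names only, the slide or the replicate number as a block, array weights, no variance trend, only the compared days in the fit, a 2-fold minimum, another detection flag, and each array left out in turn. Simulated data tested the procedure: 20 simulations per pair drew each miRNA from a normal distribution with its own mean and spread within days, and changed 20 miRNAs per fold size. At 2-fold, the share recovered was 80.8% for D11 against D10, 72.2% for D12 against D11, 79.5% for D12 against D10, 72.2% for D16 against D12 and 75.5% for D20 against D16, with a false share of at most 4.11%. The simulated miRNAs were drawn independently of each other, with no effect of slide or brightness. These shares therefore may not hold for the real arrays. Coordinates, target genes and other species' data were left out, since none came with the series. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.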

Results

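The series profiled pig conceptuses across the days on which they elongate and begin to attach to the uterus, and its stated design asks how miRNA levels differ between these days. It holds 29 arrays, with n = 9 for D10 and n = 5 each for D11, D12, D16 and D20. Per the labels, conceptuses were flushed from the uterus until D16, and on D20 trophoblast was dissected away from the embryo, so day and tissue part change together at D20. The tissue tag of D16 replicate 5 reads trophoblast while its title reads conceptus. Its values correlated with the D16 mean at r = 0.9637 and with the D20 mean at r = 0.7599 across the 218 tested miRNAs, which are not independent replicates.

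The mean number of detected miRNAs was 100.2 ± 23.4 (SD, n = 9) on D10, 115.6 ± 13.0 (n = 5) on D11, 129.4 ± 7.89 (n = 5) on D12, 146.2 ± 15.3 (n = 5) on D16 and 204 ± 13.3 (n = 5) on D20. The mean over the D16 and D20 arrays (n = 10) exceeded that over the earlier arrays (n = 19) by 63.15 miRNAs (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Within slides this difference was 66.67 on slide 1, 54.67 on slide 2, 74.67 on slide 4 and 56.25 on slide 5, and slide 3 held no D16 or D20 array. Array brightness, the intensity at the scaling percentile, moved alongside, between 139.62 and 829.97 on D10 and between 1454.2 and 3096.8 on D20. On 6 of the 9 D10 arrays it lay below that of every D11 array, and these arrays are called dim below.

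**Figure D1:**
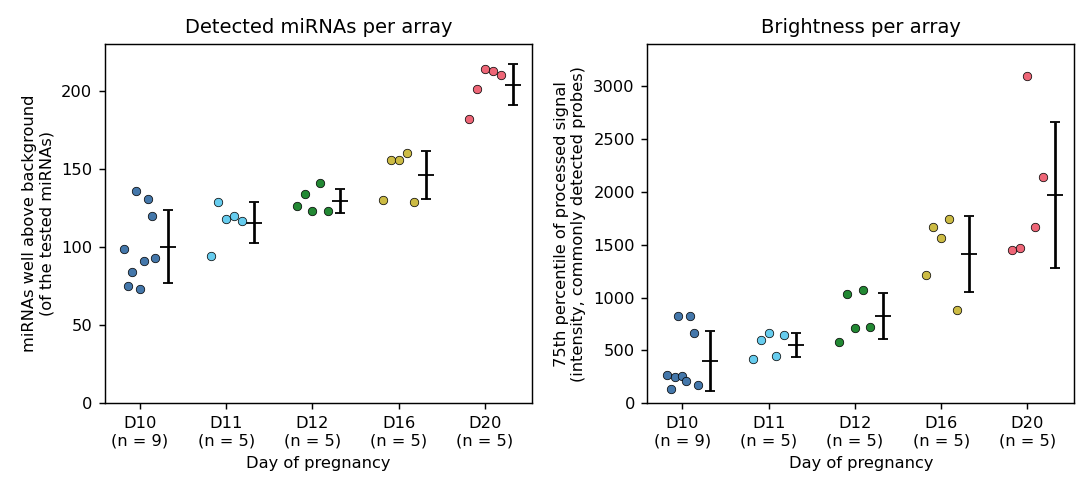
Detected miRNAs among those tested (left, a count) and brightness (right, 75th percentile of processed signal, intensity) on each of the 29 arrays by day of pregnancy, with the mean and SD of each day. Detected miRNAs ran from 73 to 136 on D10 and from 182 to 214 on D20, and the D20 arrays were brighter than every D10, D11 and D12 array.

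Of the 218 tested miRNAs, 192 differed between days (moderated F test, adjusted p below the threshold). The smallest p belonged to hsa-miR-409-3p (F = 386.8, adjusted p = 1.99e-21), hsa-miR-431 (F = 253.7, adjusted p = 1.93e-19) and ssc-miR-758 (F = 234.8, adjusted p = 3.26e-19) of the imprinted DLK1-DIO3 locus. The others were ssc-miR-199b* (F = 272.4, adjusted p = 1.12e-19), a mesenchymal miRNA, and ssc-miR-100 (F = 238.6, adjusted p = 3.26e-19), of the miR-99 family. All of these were highest on D20 and below background on all D16 arrays. On the arrays before D20, hsa-miR-409-3p was below background throughout, mostly at the floor. Values set to the floor have little spread, so these F and p do not rest on measured precision alone. Among the 192, the highest mean fell on D20 for 115 (59.9%), on D10 for 25, on D16 for 21, on D12 for 18 and on D11 for 13. The D20 number was 69 with the authors' values and 32 with normexp. With only miRNAs detected on every array it was 18, among 43 past the F test. A miRNA could enter the test through D20 alone, where more were detected, and such a miRNA tends to be highest there. Correlations of log2 values across miRNAs had a median of 0.959 for arrays of the same day and 0.8853 for arrays of different days. Day means correlated at r = 0.9795 for D11 and D10, 0.976 for D12 and D11, 0.9372 for D16 and D12, and 0.8315 for D20 and D16. Over all 10 pairs of days, 861 differences passed the test.

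**Figure D2:**
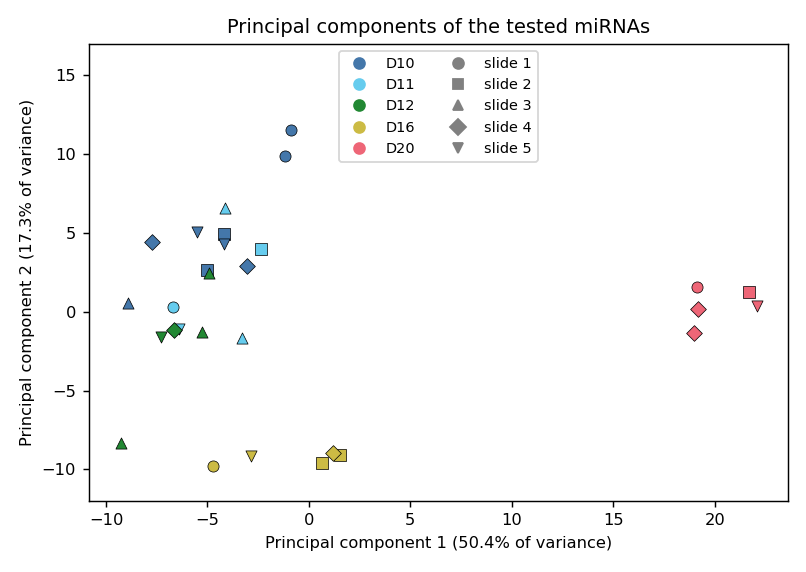
First and second principal component of the 218 tested miRNAs on 29 arrays (50.4% and 17.3% of the variance, arbitrary units), coloured by day with one symbol per slide. The D20 arrays lie apart from all others along the first component, and D10, D11 and D12 arrays overlap.

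For each named miRNA that passed, all 5 arrays of the later day lay past the mean of the earlier day, except for a few. These were hsa-miR-371-3p (3 of 5 in both D12 comparisons), and, with 4 of 5 each, ssc-miR-221 (D12 against D10) and ssc-miR-196b-5p, ssc-miR-363 and mmu-miR-144* (D20 against D16). Of the 96 named differences that passed with the miRNA detected on both days, 21 had it detected on fewer than 0.5 of the arrays of 1 day, so their size is partly against values near the floor. In 12 of these it was on a single array: ssc-miR-455 and ssc-miR-424 (D12 against D11), ssc-miR-4331, hsa-miR-134, mmu-miR-1193-3p, ssc-miR-455 and hsa-let-7d (D12 against D10), hsa-miR-557 and hsa-miR-182 (D16 against D12), and ssc-miR-199a, hsa-miR-132 and hsa-miR-219-5p (D20 against D16). The reference level depends on the scaling. The median log2 difference over all tested miRNAs, in the order D11 against D10, D12 against D11, D12 against D10, D16 against D12 and D20 against D16, was -0.13, -0.09, -0.16, 0 and 0.63. It became 0.14, -0.08, 0.19, 0.23 and -0.07 with the percentile over all probes, and 0.02, -0.04, 0.02, 0.03 and 0.08 with quantile normalization. With normexp it became -0.53, 0.07, -0.42, -0.94 and 0.12, and with the authors' values -0.04, -0.08, 0.02, -0.06 and -0.12.

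D11 against D10 asks what changes in the day before the D12 samples. ssc-miR-152, a member of the miR-148 family, was detected on 4 of 5 D11 arrays and 0 of 9 D10 arrays (adjusted p = 0.0139, no fold bound above 1), and was the only miRNA to pass. The next smallest p belonged to hsa-miR-96, a sensory-epithelium miRNA, with 0.70 ± 0.18 log2 (SE, n = 5 and 9), to ssc-miR-221 with 0.92 ± 0.26, and to ssc-miR-133a-3p, below background on both days. Each missed the threshold at an adjusted p of 0.0527. The epithelial miR-183 cluster had a median log2 difference of 0.67 (adjusted camera p = 0.0111; adjusted p = 0.748 with an estimated correlation), and with normexp the median was -0.42. None of its 3 members passed over all miRNAs and 3 were higher adjusted over the list alone.

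The miR-17 to miR-92 clusters, which promote proliferation, had a median of 0.17 (adjusted p = 0.0231; adjusted p = 0.919 with an estimated correlation) and -0.08 with normexp, and none of the 11 members passed. The imprinted DLK1-DIO3 list had a median of -0.14, or 0 with members at their bound (adjusted p = 0.0231; adjusted p = 0.919 with an estimated correlation), and none of its 22 members passed. Adjusted over the list alone, 3 members of the miR-200 family, 3 endothelial, 2 miR-29, 1 HOX, 1 striated muscle (ssc-miR-133a-3p) and the hypoxia miRNA ssc-miR-210 (0.57) were higher, and 1 mesenchymal member was lower. No list member other than these passed either way, and no other list was called. The let-7 list had a median of -0.64 (adjusted p = 0.0926) and the miR-200 family 0.50, or -0.45 with normexp, with a mean of 0.16 (adjusted p = 0.0786).

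At an unadjusted p of 0.05, 46 miRNAs passed for D11 against D10. Within slides 1, 2, 3 and 5, the miR-183 cluster median differed by 0.28, 0.54, 1.12 and 0.48, and the miR-17 to miR-92 median by -0.08, 0.31, 0.58 and 0.11. ssc-miR-152, below background on all D10 arrays, was higher on slides 2, 3 and 5 but not on slide 1. The ssc-miR-152 call was lost without D11 replicate 2 (adjusted p = 0.0728) or D11 replicate 5 (adjusted p = 0.0653) and had the opposite sign with normexp (-0.27), where the median over all miRNAs was -0.53. The miR-17 to miR-92 call was lost without D11 replicate 3 (adjusted p = 0.0784), and the DLK1-DIO3 call without D10 replicate 9 (adjusted p = 0.0549), D11 replicate 2 (adjusted p = 0.0874) or D11 replicate 4 (adjusted p = 0.0763). Without the 6 dim arrays the miR-183 median was 0.32 (adjusted p = 0.12) and the miR-17 to miR-92 median 0.05 (adjusted p = 0.98). The DLK1-DIO3 median was then 0.02 (adjusted p = 0.613), with its sign turned, and ssc-miR-152 no longer passed (adjusted p = 0.651). The number of miRNAs passing was 25 with the authors' values, 0 with normexp, 27 without D10 replicate 7, and 0 without D11 replicate 2 or D11 replicate 5.

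The list calls for D11 against D10 were lost under many other choices. For the miR-183 cluster these were the percentile over all probes (adjusted p = 0.101), normexp (0.774), the mean of all probes (0.0541) and total gene signal (0.0719). For the miR-17 to miR-92 clusters they were the percentile over all probes (0.101), quantile normalization (0.188), detection on every array (0.0999), no floor (0.0685) and pig names only (0.232). The adjusted p of fry, a test against no change, was 0.128. For the DLK1-DIO3 list the call was lost with quantile normalization (0.188), normexp (0.277), no filter (0.941), no floor (0.366), total gene signal (0.238), pig names only (0.232) and the replicate block (0.0585), and fry gave 0.189. The median of that list was 0 with no floor and with total gene signal. The median of the miR-17 to miR-92 clusters was 0.61 with the percentile over all probes and 0.40 with the authors' values, and that of the miR-183 cluster was 1.04 with the percentile over all probes.

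D12 against D11 compares the following day, with 3 miRNAs higher and 8 lower. ssc-miR-4331 rose by 2.37 ± 0.50 log2 (SE, n = 5 and 5; adjusted p = 0.00689) and ssc-miR-365-3p by 1.04 ± 0.20 (adjusted p = 0.00392). hsa-miR-498 was detected on 4 of 5 D12 arrays and 0 of 5 D11 arrays (adjusted p = 0.0119), with no fold bound above 1. What this human-named probe binds in pig RNA was not tested. ssc-miR-455 fell (-1.69 ± 0.38, adjusted p = 0.00766), as did ssc-miR-503 (-1.26 ± 0.28, adjusted p = 0.00766) and ssc-miR-424 (-1.09 ± 0.30, adjusted p = 0.0321) of the X-linked miR-424 cluster, whose members restrain the cell cycle. ssc-miR-210, induced by hypoxia through HIF1A, fell (-0.94 ± 0.27, adjusted p = 0.0418).

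In the pluripotency clusters, expressed in early embryonic cells, hsa-miR-371-3p fell (-1.65 ± 0.49, adjusted p = 0.0449), while hsa-miR-302c (0.34 ± 0.18, adjusted p = 0.283) and hsa-miR-302b (0.35 ± 0.22, adjusted p = 0.429) did not pass. The median of the 5 members was 0.31 and the mean -0.09. Of the 7 members of the miR-424 cluster, 2 were lower and 5 did not pass, ssc-miR-424* among them, which was below background on both days. hsa-miR-1280 (-1.40 ± 0.33, adjusted p = 0.00854) and hsa-miR-1274a (-0.78 ± 0.20, adjusted p = 0.0187) fell as well. Both names were later withdrawn from miRBase as fragments of transfer RNA. ssc-miR-133a-3p, known from striated muscle, passed as lower (adjusted p = 0.00854) but was below background on all arrays of both days, and its sign turned with normexp. Adjusted over the list alone, the counts for these lists were the same, and 1 member of the miR-30 family was lower. No member of any other list passed, and no list was called. The smallest adjusted camera p, 0.0727, was that of the miR-17 to miR-92 clusters (median 0.10).

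At an unadjusted p of 0.05, 42 miRNAs passed for D12 against D11. On slides 3 and 5, which held both days, all 11 kept their sign, though they were chosen with these same arrays. With slide as a block 9 of the 11 still passed, while ssc-miR-210 (-0.87, adjusted p = 0.123) and hsa-miR-371-3p (-1.67, adjusted p = 0.085) did not. Leaving out 1 array lost the calls of hsa-miR-371-3p (without 8 of the 10 arrays; adjusted p up to 0.215 without D12 replicate 5), ssc-miR-424 (7 of 10; 0.16 without D12 replicate 5), ssc-miR-210 (6 of 10; 0.191 without D12 replicate 5), hsa-miR-1274a (5 of 10; 0.0989 without D12 replicate 4) and hsa-miR-498 (without D12 replicate 5 alone; 0.0778). The split of 3 higher and 8 lower was 3 and 1 with the percentile over all probes, 4 and 3 with quantile normalization, 0 and 3 with normexp, 9 and 3 with the authors' values, and 1 and 3 when only these days were fitted.

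D12 against D10 spans the closely spaced early days, with 14 miRNAs higher and 26 lower. ssc-miR-4331 rose by 3.00 ± 0.44 log2 (SE, n = 5 and 9; adjusted p = 5.86e-05), though it was detected on only 1 of 9 D10 arrays, so the size is against values near the floor. All 3 measured members of the epithelial miR-183 cluster rose. ssc-miR-183 rose by 1.26 ± 0.21 (adjusted p = 0.000191), though it was detected on only 2 of 9 D10 arrays, so the size is partly against values below background. hsa-miR-96 rose by 0.94 ± 0.18 (adjusted p = 0.000528), and hsa-miR-182 was detected on 1 of 5 D12 arrays and 0 of 9 D10 arrays (adjusted p = 0.0106). Of the 11 members of the miR-17 to miR-92 clusters 4 rose, among them ssc-miR-17-3p by 0.67 ± 0.16 (adjusted p = 0.00673), ssc-miR-19b by 0.49 ± 0.12 (adjusted p = 0.00673) and ssc-miR-17-5p by 0.41 ± 0.11 (adjusted p = 0.0106), and 7 did not pass. In the let-7 family, which promotes differentiation, 2 of 9 members were lower, ssc-let-7c (-1.42 ± 0.46, adjusted p = 0.0297) and hsa-let-7d (-1.02 ± 0.36, adjusted p = 0.0472), and ssc-miR-98, below background on both days, did not pass (adjusted p = 0.0638).

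Among the other miRNAs higher on D12 were hsa-miR-138 (1.81 ± 0.64, adjusted p = 0.0482), hsa-miR-134 (1.23 ± 0.31, adjusted p = 0.00761; detected on 1 of 9 D10 arrays) and ssc-miR-221 (0.82 ± 0.26, adjusted p = 0.0272), an angiogenesis-related miRNA. ssc-miR-152 (adjusted p = 0.00264) and hsa-miR-498 (adjusted p = 0.0186) were each detected on 4 of 5 D12 arrays and 0 of 9 D10 arrays. The lowest were hsa-miR-370 (-2.47 ± 0.85, adjusted p = 0.042), hsa-miR-449a (-2.06 ± 0.55, adjusted p = 0.0106), ssc-miR-455 (-1.89 ± 0.33, adjusted p = 0.000356) and hsa-miR-371-3p (-1.75 ± 0.43, adjusted p = 0.00726). mmu-miR-1193-3p, hsa-miR-634, hsa-miR-1281 and hsa-miR-940 fell, with differences of -1.91, -1.81, -1.73 and -1.55. Without the 6 dim D10 arrays these were -0.33, -0.43, -0.30 and -0.14, and none passed.

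By list, the miR-183 cluster had a median of 0.94 (adjusted camera p = 0.000226; adjusted p = 0.343 with an estimated correlation) and -0.10 with normexp. The miR-17 to miR-92 median was 0.26, or 0.25 with members at their bound (adjusted p = 0.000108; adjusted p = 0.772 with an estimated correlation), and 6 members were higher adjusted over the list alone. The let-7 median was -1.11 (adjusted p = 0.0328; adjusted p = 0.919 with an estimated correlation), and all 9 members were lower adjusted over the list alone. In the miR-99 and miR-125 families, ssc-miR-125b fell (-1.44 ± 0.49, adjusted p = 0.0406), 3 of 4 did not pass, ssc-miR-99a (-1.09 ± 0.43, adjusted p = 0.0686) among them, and 3 were lower adjusted over the list alone. In the miR-424 cluster, ssc-miR-503 fell (-0.96 ± 0.25, adjusted p = 0.0104), 6 of 7 did not pass and 4 were lower adjusted over the list alone.

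In the DLK1-DIO3 list, 1 member rose (hsa-miR-134), 2 fell (hsa-miR-370 and hsa-miR-539, the latter below background on both days) and 19 did not pass. Adjusted over the list alone 1 was higher and 0 lower. A single member was lower in the mesenchymal list (ssc-miR-199b of 6, below background on both days), the miR-34 and miR-449 family (hsa-miR-449a of 4), the miR-15 and miR-16 family (ssc-miR-195 of 4, below background on D12), the miR-30 family (ssc-miR-30d of 8, -0.58 ± 0.15, adjusted p = 0.0104) and the pluripotency clusters (hsa-miR-371-3p of 5, with a median of 0.03 and a mean of -0.31). In the endothelial list ssc-miR-221 was higher and 6 of 7 did not pass, ssc-miR-222 (0.71 ± 0.33, adjusted p = 0.115) among them. Adjusted over the list alone, the counts of these 6 lists were the same. No member of the erythroid list passed, and 2 of its 4 were lower adjusted over the list alone. Of the remaining lists none had a member that passed, and no list but the miR-183, miR-17 to miR-92 and let-7 lists was called.

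At an unadjusted p of 0.05, 79 miRNAs passed for D12 against D10. The number past the adjusted threshold was 8 (4 higher and 4 lower) without the 6 dim D10 arrays, among them ssc-miR-4331, ssc-miR-183, hsa-miR-498 and ssc-miR-455, and 17 (9 and 8) with slide as a block. It was 24 without D12 replicate 2 and 123 (15 higher and 108 lower) with no filter. The split of 14 and 26 was 17 and 6 with the percentile over all probes, 22 and 21 with quantile normalization, 0 and 5 with normexp and 34 and 31 with the authors' values. With normexp ssc-miR-152, ssc-miR-183, hsa-miR-134, hsa-miR-498, ssc-miR-221 and hsa-miR-182 had the opposite sign (-0.10 to -0.33), but the median over all miRNAs was then -0.42 and all of these lay above it. Within slides 3, 4 and 5 the miR-183 median was 1.34, 0.71 and 1.20, the miR-17 to miR-92 median 0.66, 0.31 and 0.14, and the let-7 median -0.13, -0.21 and -0.64. With slide as a block they were 0.95 (adjusted p = 0.000312), 0.30 (adjusted p = 0.000111) and -0.71 (adjusted p = 0.189), so the let-7 call ended. Of the 28 named miRNAs that passed, 12 did so with slide as a block. Differences under the block are given before the adjusted p for miRNAs detected on both days. Both let-7 members (ssc-let-7c, -1.06, adjusted p = 0.195, and hsa-let-7d, -0.95, 0.157) and hsa-miR-182 (0.0597) were lost, which leaves 2 of 3 in the miR-183 cluster. So were hsa-miR-138 (1.825, 0.12), hsa-miR-134 (1.03, 0.058), hsa-miR-498 (0.0763), ssc-miR-221 (0.82, 0.0929), hsa-miR-370 (-2.945, 0.0538), hsa-miR-449a (-1.89, 0.0646), ssc-miR-125b (-1.225, 0.166) and ssc-miR-30d (-0.55, 0.0539). The others were hsa-miR-634 (-1.16, 0.0605), hsa-miR-1281 (-1.195, 0.0758), hsa-miR-940 (-0.99, 0.12), hsa-miR-539 (0.139) and ssc-miR-195 (0.107). The let-7 call was also lost without D10 replicate 7 (adjusted p = 0.0544), D10 replicate 8 (adjusted p = 0.071), D12 replicate 1 (adjusted p = 0.0645) or D12 replicate 2 (-0.67, adjusted p = 0.125). Further choices that lost it were normexp (adjusted p = 0.145), no filter (0.131), detection on every array (0.18), pig names only (0.0543), the replicate block (0.107) and array weights (0.114). For let-7, fry, against no change, gave an adjusted p of 0.0567. The miR-183 call was lost with normexp (adjusted p = 0.312). Without the dim arrays the miR-17 to miR-92 median was 0.13 (adjusted p = 0.051), the miR-183 median 0.60 (adjusted p = 0.0064) and the let-7 median -1.15 (adjusted p = 0.00618). With the percentile over all probes these medians were 0.81, 1.49 and -0.56, and with the authors' values 0.66, 0.97 and -0.65, all still called. With normexp the miR-17 to miR-92 median was 0.10, still called, and the let-7 median -0.62. Without D12 replicate 2 the adjusted p was 0.162 for ssc-let-7c, 0.178 for hsa-let-7d, 0.175 for ssc-miR-125b, 0.122 for ssc-miR-195 and 0.0759 for hsa-miR-539. It was just over the threshold for mmu-miR-1193-3p (0.0522), hsa-miR-634 (0.056), hsa-miR-1281 (0.0578) and hsa-miR-940 (0.0636). Each array was left out in turn, in 14 runs. This lost hsa-miR-138 and ssc-miR-195 in 10 of them, hsa-miR-370 in 9, hsa-let-7d in 8, hsa-miR-539 in 7, ssc-miR-125b in 6, ssc-let-7c in 4, ssc-miR-221 and hsa-miR-940 in 2, and hsa-miR-498, mmu-miR-1193-3p, hsa-miR-634 and hsa-miR-1281 in 1. The largest adjusted p was 0.137 for hsa-miR-138 and 0.0886 for hsa-miR-498 (both without D12 replicate 5), 0.0959 for ssc-miR-221 (without D12 replicate 3) and 0.0933 for hsa-miR-370 (without D12 replicate 1).

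D16 against D12 covers the days from elongation to early attachment, with 29 miRNAs higher and 25 lower. hsa-miR-375, known from endocrine and epithelial cells, was at least 3.37-fold higher on D16 (adjusted p = 1.82e-09), ssc-miR-196b-5p of the HOX clusters at least 3.11-fold (adjusted p = 0.000158), and ssc-miR-126, the endothelial miRNA within EGFL7, at least 1.47-fold (adjusted p = 0.000189). All were below background on all D12 arrays. ssc-miR-296 rose by 2.40 ± 0.37 log2 (SE, n = 5 and 5; adjusted p = 3.04e-05) and hsa-miR-557 by 2.05 ± 0.28 (adjusted p = 5.68e-06). All 5 measured pluripotency miRNAs fell, including hsa-miR-302a (-1.15 ± 0.23, adjusted p = 0.000486) and hsa-miR-302b (-1.12 ± 0.22, adjusted p = 0.000346), and hsa-miR-371-3p was at least 3.51-fold lower (adjusted p = 0.000421). Of the miR-34 and miR-449 family, which act in ciliated cells and downstream of p53, mmu-miR-34b-5p was at least 11.9-fold lower (adjusted p = 3.51e-05), ssc-miR-34c at least 5.1-fold (adjusted p = 0.000814) and hsa-miR-449a at least 2.06-fold (adjusted p = 0.0475).

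Further miRNAs that rose were hsa-miR-1249 (2.37 ± 0.39, adjusted p = 6.35e-05), hsa-miR-1225-5p (2.26 ± 0.48, adjusted p = 0.000671) and ssc-miR-149 (1.75 ± 0.35, adjusted p = 0.000377). Those that fell included hsa-miR-138 (-3.17 ± 0.73, adjusted p = 0.00138), ssc-miR-4331 (-2.70 ± 0.50, adjusted p = 0.000194), hsa-miR-765 (-2.08 ± 0.55, adjusted p = 0.00542) and hsa-miR-483-5p (-1.70 ± 0.49, adjusted p = 0.0105). ssc-miR-221 and ssc-miR-222, which share a cluster, were at least 2.1-fold (adjusted p = 0.000158) and 2.08-fold lower (adjusted p = 0.000976). The liver miRNA ssc-miR-122 was at least 1.12-fold higher (adjusted p = 0.000976).

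The pluripotency list had a median of -1.12 (adjusted camera p = 0.000551; adjusted p = 0.586 with an estimated correlation). The miR-34 and miR-449 list, with 3 of 4 members lower, had -2.33, or -1.70 with members at their bound (adjusted p = 0.0454; adjusted p = 0.816 with an estimated correlation). In the endothelial list 4 of 7 members were higher, among them hsa-miR-132 (4 of 5 D16 arrays, 0 of 5 D12 arrays; adjusted p = 4.04e-08), and 2 were lower. Its median was 0.52, 0 with members at their bound and -0.86 with normexp. The miR-30 family had 2 of 8 higher, ssc-miR-30e-5p (at least 1.29-fold, adjusted p = 0.000588) and ssc-miR-30a-5p (1.02 ± 0.37, adjusted p = 0.0422), and 3 adjusted over the list alone. In the miR-200 family, which maintains epithelial identity, mmu-miR-429 rose (0.87 ± 0.21, adjusted p = 0.00226), and 6 of 7 did not pass, hsa-miR-200a (0.67 ± 0.26, adjusted p = 0.0553) and hsa-miR-141 (1.06 ± 0.57, adjusted p = 0.208) among them. ssc-miR-26a rose (1.22 ± 0.34, adjusted p = 0.00667) and ssc-miR-29c fell (-1.62 ± 0.27, adjusted p = 6.45e-05), while ssc-miR-29a did not pass.

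Other lists held members that went both ways. The miR-183 cluster had hsa-miR-182 higher (0.65 ± 0.19, adjusted p = 0.0122), hsa-miR-96 lower (-0.63 ± 0.20, adjusted p = 0.0242) and ssc-miR-183 not past the test (-0.62 ± 0.24, adjusted p = 0.0553) except adjusted over the list alone. The miR-17 to miR-92 clusters had ssc-miR-92a higher (0.73 ± 0.25, adjusted p = 0.0303), ssc-miR-17-5p lower (-0.36 ± 0.12, adjusted p = 0.0314) and 9 not passing. The HOX clusters had ssc-miR-196b-5p higher, ssc-miR-10b lower (-1.20 ± 0.32, adjusted p = 0.00572) and 2 of 4 not passing. The neural list had hsa-miR-218 higher (at least 1.1-fold, adjusted p = 0.000425), ssc-miR-128 lower (-0.79 ± 0.19, adjusted p = 0.00263) and 2 of 4 not passing. For lists not mentioned otherwise, counts adjusted over the list alone were the same. The let-7, miR-99 and miR-125, mesenchymal, erythroid, leukocyte, striated muscle, DLK1-DIO3, miR-424, miR-15 and miR-16, miR-23, miR-24 and miR-27, and hypoxia lists had no member past the test, and none of these was called.

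At an unadjusted p of 0.05, 73 miRNAs passed for D16 against D12. On slides 4 and 5, with 1 array of each day, 52 of the 54 kept their sign, though they were chosen with these same arrays. The pluripotency median there was -0.31 and -1.57, and the miR-34 and miR-449 median -3.39 and -2.12. The miR-34 and miR-449 call was lost without D12 replicate 3 (adjusted p = 0.0686), D12 replicate 4 (0.0785), or D16 replicates 1 (0.056), 4 (0.0589) or 5 (0.068). It was also lost with normexp (adjusted p = 0.0736), the mean of all probes (0.0754), the replicate block (0.088) and a fit of only the compared days (0.121). The pluripotency call was lost with normexp, where the median was -0.86 (adjusted p = 0.261), close to that of all miRNAs. With slide as a block 29 of 34 named miRNAs still passed, and ssc-miR-92a (adjusted p = 0.153), ssc-miR-17-5p (0.0842), hsa-miR-449a (0.0916), ssc-miR-26a (0.127) and ssc-miR-30a-5p (0.232) did not. hsa-miR-449a was lost without 7 of the 10 arrays (up to 0.165 without D12 replicate 3), ssc-miR-30a-5p without 7 (up to 0.137 without D12 replicate 2), and ssc-miR-92a, ssc-miR-17-5p and hsa-miR-96 were lost without 5, 5 and 3 (up to 0.112, 0.0895 and 0.0687, each without D16 replicate 5). The split of 29 and 25 was 38 and 13 with the percentile over all probes, 24 and 32 with the authors' values and 2 and 18 with normexp. Under normexp, with a median over all miRNAs of -0.94, hsa-miR-375 (-0.12), ssc-miR-196b-5p (-0.28), hsa-miR-557 (-0.35), ssc-miR-126 (-0.53), hsa-miR-132 (-0.86), hsa-miR-182 (-0.87), ssc-miR-92a (-0.86), hsa-miR-218 (-0.69), ssc-miR-122 (-0.85) and ssc-miR-30e-5p (-0.81) had the opposite sign.

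D20 against D16 compares the last days, in which the sampled tissue also changed from flushed conceptus to dissected trophoblast. ssc-miR-451, abundant in red blood cells, was the most raised miRNA, with 5.29 ± 1.04 log2 (SE, n = 5 and 5; adjusted p = 7.36e-05), and hsa-miR-144 from the same cluster rose by 3.65 ± 0.56 (adjusted p = 1.92e-06). All 6 mesenchymal miRNAs rose, with ssc-miR-199a* up by 4.60 ± 0.25 (adjusted p = 7.75e-16), ssc-miR-199a by 4.06 ± 0.21 (adjusted p = 4.32e-16; detected on 1 of 5 D16 arrays), and ssc-miR-199b* and ssc-miR-214 at least 7.19-fold and 6.67-fold higher. All 9 let-7 members and all 4 of the miR-99 and miR-125 families rose, with hsa-let-7d up by 3.90 ± 0.41 (adjusted p = 2.22e-09) and ssc-miR-125b by 3.95 ± 0.56 (adjusted p = 5.82e-07). At the imprinted DLK1-DIO3 locus 18 of 22 members rose, hsa-miR-377 by 3.66 ± 0.17 (adjusted p = 4.12e-17). Pluripotency miRNAs fell, with hsa-miR-302c at -0.97 ± 0.18 (adjusted p = 2.72e-05) and hsa-miR-302b at -0.83 ± 0.22 (adjusted p = 0.00169).

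Further miRNAs that rose most were ssc-miR-335, encoded in the imprinted MEST gene (3.88 ± 0.27, adjusted p = 3.02e-13), and hsa-miR-483-3p, encoded in IGF2 (at least 8.59-fold, adjusted p = 2.81e-16). The lowest were hsa-miR-1225-5p (-1.68 ± 0.48, adjusted p = 0.00324), hsa-miR-1249 (-1.45 ± 0.39, adjusted p = 0.00201), ssc-miR-296 (-1.41 ± 0.37, adjusted p = 0.00161), hsa-miR-188-5p (-1.38 ± 0.47, adjusted p = 0.0125), ssc-miR-196b-5p (-1.31 ± 0.38, adjusted p = 0.00399), hsa-miR-642b (-1.21 ± 0.38, adjusted p = 0.00607), bta-miR-671 (-1.20 ± 0.49, adjusted p = 0.0349) and hsa-miR-134 (-1.10 ± 0.35, adjusted p = 0.00755). Of these, hsa-miR-1225-5p, hsa-miR-1249, ssc-miR-296 and ssc-miR-196b-5p had risen from D12 to D16.

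**Figure D3:**
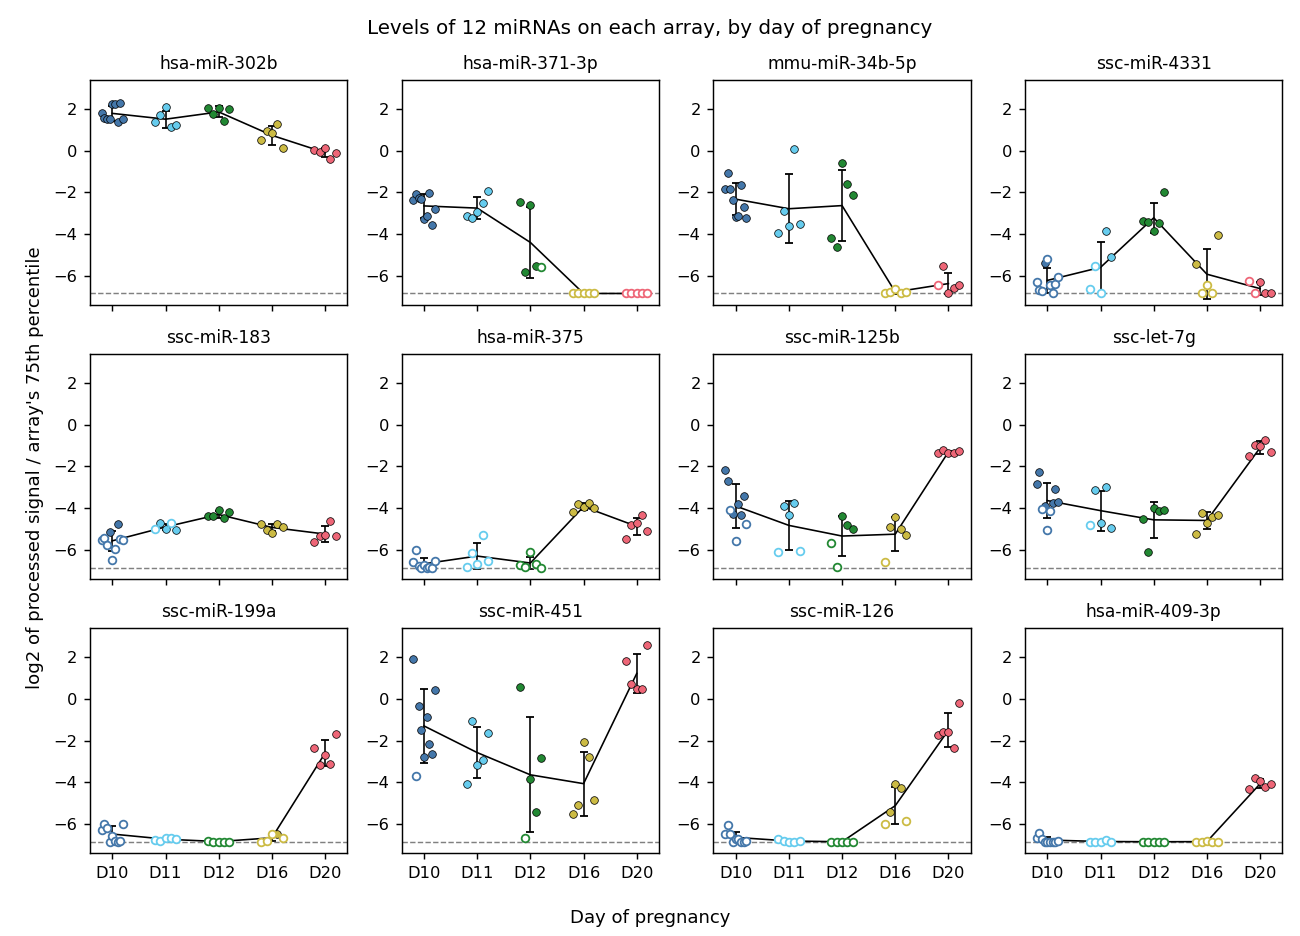
Levels of 12 miRNAs (log2 of processed signal over the array's 75th percentile) on each array by day of pregnancy, with means with SD and the floor as a dashed line. Filled points mark arrays with any probe of the miRNA above background, open points those with none. The level is that of the kept probe, so a filled point can lie at the floor. ssc-miR-451 lay at 1.22 on average on D20 against -4.07 on D16.

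Of the lists, 4 were called. The mesenchymal list had a median of 3.42, or 2.79 with members at their bound (adjusted camera p = 0.00194; adjusted p = 0.772 with an estimated correlation). The DLK1-DIO3 list had a median of 1.68, or 1.04 at the bound (adjusted p = 5.93e-05; adjusted p = 0.816 with an estimated correlation). In it hsa-miR-134 was lower, 3 members did not pass, and hsa-miR-409-3p, hsa-miR-431 and ssc-miR-758 were at least 4.42-fold, 3.66-fold and 5.6-fold higher. The X-linked miR-424 cluster had all 7 members higher, among them ssc-miR-450c-5p (at least 3.68-fold), ssc-miR-542-3p (at least 3.18-fold) and ssc-miR-542-5p (at least 2.09-fold), with a median of 2.31, or 1.67 at the bound (adjusted p = 0.0135; adjusted p = 0.816 with an estimated correlation). The pluripotency list had 4 of 5 members lower and a median of -0.79 (adjusted p = 0.0135; adjusted p = 0.772 with an estimated correlation). Within slides 1, 2, 4 and 5 the mesenchymal median was 3.44, 3.45, 3.12 and 4.12, the DLK1-DIO3 median 1.36, 2.08, 1.60 and 1.78, the miR-424 median 1.96, 2.08, 2.31 and 2.30, and the pluripotency median -0.53, -0.93, -1.13 and -0.23.

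Each of these 4 calls was lost under some other choice. The DLK1-DIO3 and miR-424 medians were 0.89 and 1.40 with quantile normalization and 0.99 and 1.19 with the authors' values, still called. With normexp the mesenchymal median was 1.34 (adjusted p = 0.108), the DLK1-DIO3 median 0.38 (adjusted p = 0.917) and the miR-424 median 0.62 (adjusted p = 0.606). With no floor the mesenchymal (adjusted p = 0.175) and miR-424 (adjusted p = 0.0773) calls were lost. The pluripotency call was lost with the percentile over all probes (-1.72, adjusted p = 0.2), quantile normalization (-0.98, adjusted p = 0.167) and the authors' values (-1.49, adjusted p = 0.0619).

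The let-7 list had a median of 2.81 (2.27 at the bound) with ssc-let-7g up by 3.49 ± 0.45 (adjusted p = 1.39e-07) and ssc-miR-98 at least 4.56-fold higher. The miR-99 and miR-125 families had 2.96 (2.65 at the bound) with ssc-miR-100 at least 7.21-fold and ssc-miR-99b at least 1.46-fold higher. Neither was called against the other miRNAs (adjusted p = 0.221 and 0.125). In the endothelial list 5 of 7 members rose, ssc-miR-126 by 3.63 ± 0.32 (adjusted p = 5.64e-11) and ssc-miR-126* at least 1.65-fold, and 2 fell, hsa-miR-132 (-0.98 ± 0.10, adjusted p = 3.13e-09) and ssc-miR-296. Its median was 1.09 (0.45 at the bound), while the test's direction was lower (adjusted p = 0.773). In the erythroid list 3 of 4 rose, mmu-miR-144* at least 1.85-fold, and 1 did not pass, with a median of 2.57 (2.27 at the bound, adjusted p = 0.773). The leukocyte miRNA hsa-miR-223 was at least 2.44-fold higher (adjusted p = 0.00833), ssc-miR-133a-3p of striated muscle at least 1.25-fold, and ssc-miR-122 of liver rose by 2.07 ± 0.23 (adjusted p = 4.61e-09). In the neural list 3 of 4 rose, with hsa-miR-218 up by 3.42 ± 0.26 (adjusted p = 2.2e-12) and ssc-miR-9-1 at least 1.89-fold higher. The other was hsa-miR-219-5p, up by 0.64 ± 0.23 (adjusted p = 0.0162) but with the opposite sign under the percentile over all probes, normexp and the authors' values. In the HOX clusters ssc-miR-10a (2.48 ± 0.58, adjusted p = 0.000558) and ssc-miR-10b (2.45 ± 0.32, adjusted p = 1.7e-07) rose, ssc-miR-196b-5p fell and 1 of 4 did not pass. The median was 1.19 and the test's direction lower (adjusted p = 0.773).

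All 4 members of the miR-15 and miR-16 family rose (median 1.02), among them ssc-miR-195 (at least 2.19-fold), ssc-miR-15a (1.17 ± 0.29) and ssc-miR-16 (0.86 ± 0.17, but -0.06 with the percentile over all probes). So did all 5 of the miR-23, miR-24 and miR-27 clusters (median 1.95), with ssc-miR-27a at 2.21 ± 0.49, ssc-miR-27b at 1.91 ± 0.43 and ssc-miR-23b at 1.41 ± 0.27. In the miR-30 family 7 of 8 rose (median 1.19), with ssc-miR-30c at 1.56 ± 0.26, ssc-miR-30b-5p at 1.44 ± 0.23 and ssc-miR-30a-3p at 1.21 ± 0.17, and both miR-29 members (ssc-miR-29a 1.54 ± 0.41, ssc-miR-29c 1.42 ± 0.27) and ssc-miR-26a (1.42 ± 0.34) rose. In the miR-200 family hsa-miR-200c rose (1.59 ± 0.58, adjusted p = 0.0181), another member rose. mmu-miR-429 (-0.61 ± 0.21, adjusted p = 0.0125) and hsa-miR-200a* (-0.42 ± 0.16, adjusted p = 0.0249) fell and 3 did not pass, with a median of -0.35 and a mean of 0.15. In the miR-17 to miR-92 clusters ssc-miR-92a was 2-fold lower (adjusted p = 0.000881), ssc-miR-363 was higher (0.55 ± 0.21, adjusted p = 0.0249) but had the opposite sign under all 4 other scalings. The other 9 of 11 did not pass, bta-miR-25 (0.30 ± 0.14, adjusted p = 0.0643, with the opposite sign under quantile normalization and the authors' values) among them. ssc-miR-34a rose (0.95 ± 0.29, adjusted p = 0.00561) and the other 3 of the miR-34 and miR-449 family did not pass. The list median was 0.22, and -0.03, -0.31 and -0.42 with the percentile over all probes, normexp and the authors' values. None of the 3 miR-183 members passed (median -0.11), and the hypoxia miRNA ssc-miR-210 did not (0.19, but -0.73, -0.72 and -0.56 with the percentile over all probes, quantile normalization and the authors' values). The counts adjusted over the list alone were the same, except that ssc-miR-363 did not pass in its list. None of these lists was called. The primate chromosome 19 list, which as fixed did not include hsa-miR-498, had 23 names on the array and no tested member in any comparison.

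**Figure D4:**
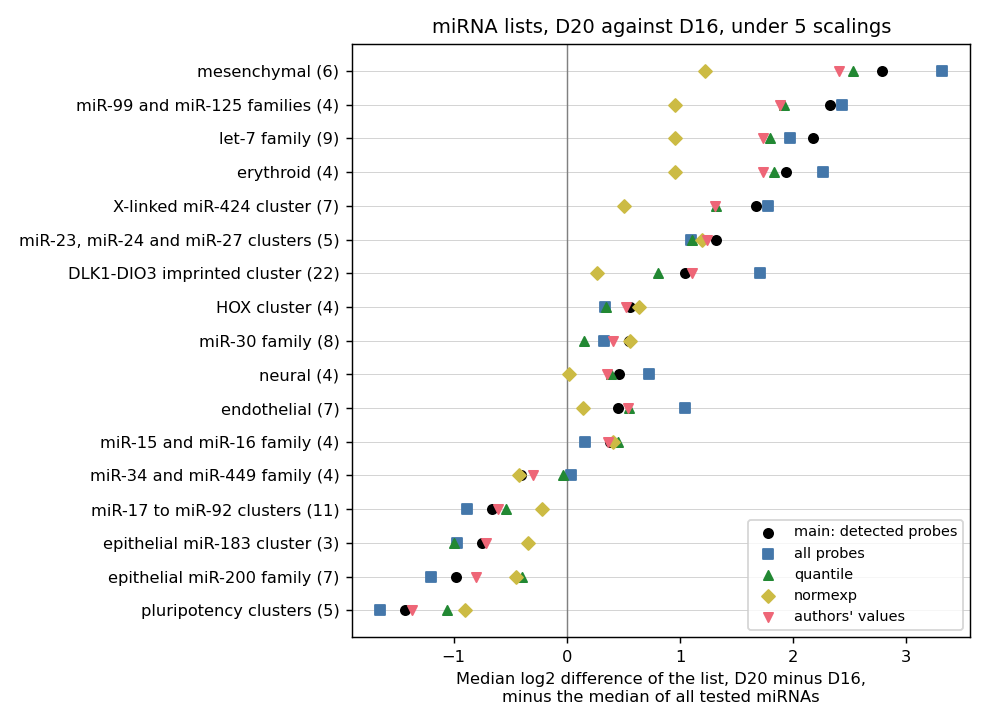
Median log2 difference, D20 minus D16, of each list with at least 3 tested members (number in brackets) minus the median of all 218 tested miRNAs, under 5 scalings. The mesenchymal median lay 2.79 above that of all miRNAs in the main scaling and 1.22 to 3.32 above it in the others, and the pluripotency median lay below it under all 5, while the miR-34 and miR-449 median changed side.

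In total 117 miRNAs were higher and 22 lower on D20 than on D16, and 143 passed at an unadjusted p of 0.05. The median difference of the 117 was 1.60, or 1.42 with the 41 that were below background on D16 at their bound. The share higher, 84.2% of 139, was 49.6% of 135 with the percentile over all probes, 57% of 151 with quantile normalization, 81.4% of 43 with normexp and 46.4% of 151 with the authors' values. Under the main scaling and the 3 others without normexp, all 6 mesenchymal, 15 of 18 DLK1-DIO3, 6 of 9 let-7, 6 of 7 miR-424, 3 of 4 miR-99 and miR-125, 3 of 5 endothelial and 2 of 3 erythroid miRNAs stayed called higher, as did both HOX members, 2 of 3 neural members and ssc-miR-122. So did 2 of 5 in the miR-23, miR-24 and miR-27 clusters and 1 of 4 in the miR-15 and miR-16 family, but 0 of 7 miR-30, 0 of 2 miR-29 members, and neither ssc-miR-26a, hsa-miR-223 nor ssc-miR-133a-3p. On slides 1, 2, 4 and 5, 138, 139, 135 and 138 of the 139 kept their sign. The 139 were chosen with these same arrays, so this is no independent check. Leaving out 1 array lost the calls of bta-miR-671 (without D16 replicate 1, adjusted p = 0.074; D16 replicate 5, 0.103; D20 replicate 2, 0.101; D20 replicate 5, 0.0535), hsa-miR-200c (D16 replicate 1, 0.055), hsa-miR-219-5p (D20 replicate 1, 0.0975), hsa-miR-200a* (3 of 10 arrays, up to 0.0745 without D20 replicate 5) and ssc-miR-363 (5 of 10, up to 0.144 without D20 replicate 5).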

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

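A value was picked out when it stood apart from the other arrays of its day by more than Dixon's 95% limit for its gap over the whole range. This held for 11 of the 169 groups of arrays tested (6.51%), where chance alone picks about 1 in 20. D12 replicate 5 gave 4 of the 11, and no technical or biological explanation was tested for these values. In D12 replicate 5, hsa-miR-138 lay at 0.394 on the log2 scale against -1.069 for the nearest array of its day, hsa-miR-370 at -2.225 against -4.449, and ssc-miR-4331 at -1.992 against -3.381. All of these were high, and ssc-miR-19b was low in the same array, at 1.533 against 1.674. In D16 replicate 5, whose tissue tag differs from its title, hsa-miR-367 was low at 0.432 against 1.332, and hsa-miR-96 was low at -2.744 against -2.368. ssc-miR-26a was low in D16 replicate 1, at -2.61 against -2.13. On D20, ssc-miR-10b was high in replicate 2, at -0.645 against -1.314, ssc-miR-199b* was high in replicate 5, at -2.812 against -3.428, and ssc-miR-27a was low in replicate 3, at -2.445 against -2.106. ssc-miR-503 was low in D11 replicate 4, at -3.212 against -2.651.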

How the results depend on the processing

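The settings without the dim D10 arrays and without D20 were chosen after seeing the data. Signal over background limited what could be measured: only 55 of the 218 miRNAs were detected on every array, and 41 of the 117 called higher on D20 than on D16 were below background on all D16 arrays. Where no cause is given below, the cause was not tested. The counts for D16 against D12 and D20 against D16 and the F test stayed within 1.5 times their reported value except where listed. The normexp correction was run on median signals, since the files hold no mean signals. Of the 175 named values, 123 kept direction and side of the threshold with the percentile over all probes, 145 with quantile normalization, 135 with the authors' values, 75 with normexp, 162 with no filter, 125 with no floor, 151 with slide as a block and 169 without a variance trend. With the other detection flag the difference in detected miRNAs was 38.06.

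With the percentile over all probes, the counts were 4 (D11 against D10), 4 (D12 against D11) and 23 (D12 against D10), and on D20 against D16 ssc-miR-363 (-0.113), hsa-miR-219-5p (-0.114) and ssc-miR-16 (-0.063) reversed. With quantile normalization, the counts were 11 (D11 against D10) and 7 (D12 against D11), and ssc-miR-363 (-0.08) and bta-miR-25 (-0.456) reversed on D20 against D16. With the authors' values, the counts were 25 (D11 against D10) and 65 (D12 against D10), 69 miRNAs were highest on D20, and ssc-miR-363 (-0.276), bta-miR-25 (-0.417) and hsa-miR-219-5p (-0.244) reversed on D20 against D16.

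With normexp, the counts were 0, 3, 5, 20 and 43 in the order of the pairs, 552 over all pairs, 5 lists were called and 32 miRNAs were highest on D20. Reversed were ssc-miR-152 on D11 against D10 (-0.273) and ssc-miR-133a-3p on D12 against D11 (0.01). On D12 against D10 these were ssc-miR-152 (-0.172), ssc-miR-183 (-0.102), hsa-miR-134 (-0.19), hsa-miR-498 (-0.201), ssc-miR-221 (-0.272) and hsa-miR-182 (-0.329). On D16 against D12 they were hsa-miR-375 (-0.117), ssc-miR-196b-5p (-0.277), hsa-miR-557 (-0.351), ssc-miR-126 (-0.53), ssc-miR-92a (-0.856), hsa-miR-182 (-0.874), hsa-miR-132 (-0.856), hsa-miR-218 (-0.691), ssc-miR-122 (-0.852) and ssc-miR-30e-5p (-0.812). On D20 against D16 they were ssc-miR-363 (-0.176) and hsa-miR-219-5p (-0.154), below a median over all miRNAs of 0.12. That median was -0.42 on D12 against D10 and -0.94 on D16 against D12. All miRNAs listed as reversed on these earlier pairs lay above the median of their pair.

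With no filter, 123 miRNAs passed on D12 against D10, 31 lists were called, and the DLK1-DIO3 list on D11 against D10 (median -0.141) changed the direction of its test. With only the 55 miRNAs detected on every array, fewer could pass: 43 by the F test, 6, 10, 17 and 25 from D12 against D11 onwards, 202 over all pairs and 5 lists, with 18 highest on D20. With pig names only, and so 129 miRNAs tested, 115 passed the F test, 10, 7, 18 and 28 the first 4 pairs, and 540 all pairs, with 6 lists called. With no floor, 11 (D11 against D10) and 5 (D12 against D11) passed, the median correlation within days was 0.8823, and ssc-miR-195 on D12 against D10 reversed (2.051). With the mean of all probes, 2 and 6 passed on D11 against D10 and D12 against D11, and with total gene signal 17 and 7. Under total gene signal ssc-miR-199b and hsa-miR-539 on D12 against D10 reversed, each with a difference that rounds to 0.

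With slide as a block, 2 passed on D11 against D10 and 17 on D12 against D10. The replicate numbers were not taken to pair the samples: 24 of 50 correlations between arrays of the same number exceeded 0.1, with a median of 0.0958 (-0.603 to 0.542). No values for arrays of different numbers are given for comparison, so pairing stays undecided. With a replicate block over replicates 1 to 5, 15 passed on D11 against D10. With array weights, 16, 46, 61 and 89 passed in the first 4 pairs, and with no variance trend 11 on D11 against D10. With only the compared days in the fit, and so fewer samples, 4 passed on D12 against D11 and 16 on D12 against D10. Without the dim D10 arrays 8 passed on D12 against D10 and hsa-miR-539 reversed (0.022), and without D20 102 passed the F test, both with fewer samples. With a 2-fold minimum, a stricter threshold, 22 passed on D12 against D10 and 573 over all pairs. With an estimated correlation 0 lists were called, with fry 20.

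Leaving out 1 array gave 0 to 27 on D11 against D10, 6 to 19 on D12 against D11 and 24 to 55 on D12 against D10. D11 against D10 gave 0 without D11 replicate 2 or D11 replicate 5, 3 without D10 replicate 1, 4 without D10 replicate 2, 6 without D11 replicate 4, 10 without D11 replicate 1, 14 without D10 replicate 4 and 27 without D10 replicate 7. D12 against D11 gave 7 without D11 replicate 2, D11 replicate 3, D12 replicate 2 or D12 replicate 4, 19 without D12 replicate 3 and 6 without D12 replicate 5. D12 against D10 gave 24 without D12 replicate 2. The other ranges stayed within 1.5 times the reported value: 184 to 196 by the F test, 43 to 53 on D16 against D12, 132 to 140 on D20 against D16, 818 to 904 over all pairs and 10 to 14 lists. Of 2041 named values with 1 array left out, 1863 kept direction and side of the threshold, 132 no longer passed and 36 passed anew. Among values that passed 0 reversed, and 10 that passed neither way changed sign.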

Other observations

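ssc-miR-451, abundant in red blood cells, was detected on 8 of 9 D10 arrays, well before its D20 level, at -1.30 ± 1.76 (SD, n = 9) on the log2 scale. Its means were -2.58 ± 1.23 on D11, -3.64 ± 2.76 on D12, -4.07 ± 1.53 on D16 and 1.22 ± 0.95 on D20 (n = 5 each). hsa-miR-144, from the same cluster, was detected on 0 of 9 D10, 0 of 5 D11, 1 of 5 D12, 2 of 5 D16 and 5 of 5 D20 arrays. Both were looked at after their values were seen.

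hsa-miR-720, hsa-miR-1274a, hsa-miR-1274b and hsa-miR-1280, names later withdrawn from miRBase as transfer RNA fragments and chosen here after their values were seen, differed between D12 and D10 by -1.28 ± 0.28, -0.96 ± 0.18, -1.18 ± 0.21 and -0.92 ± 0.29 log2 (SE, n = 5 and 9). Their adjusted p values were 0.00264, 0.000442, 0.000356 and 0.0281. All were negative under every scaling, except that hsa-miR-720 was 0 under quantile normalization, and none passed with the percentile over all probes (-0.73, -0.41, -0.63 and -0.37). Quantile normalization also lost hsa-miR-720 and hsa-miR-1274a (adjusted p = 0.417). The authors' values lost hsa-miR-1274a (0.0527) and hsa-miR-1280 (0.239), and slide as a block lost hsa-miR-1280 (0.127). Without the 6 dim D10 arrays the differences were -0.83, -0.86, -0.89 and -0.79, and hsa-miR-1274a alone passed (adjusted p = 0.0355).

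In the paragraphs that follow, the tests of scaling and of brightness on D20, those of blood cells and the divisions within slides were chosen after the result was seen. First, 26 miRNAs were lower on D12 than on D10. Signal that does not follow the RNA on dim arrays may contribute. Over the 9 D10 arrays the scaled values of the 26 had a median slope on log2 brightness of -0.299 (quartiles -0.738 and -0.154). This slope neither reached nor excluded the size such a cause would need. It was 0.027 for 51 miRNAs outside the 26 that were detected on every D10 array. The 26 did not have to be detected there and were chosen with these arrays, so the comparison is not like for like. Without the 6 dim D10 arrays the median difference of the 26 was -0.774 against -1.217 with them, 0.636 of its size, with 24 of 26 of the same sign and 3 still called. Of the 26, 5 were below background on all arrays of both days, so their fall is not a measured one. With no filter on dim probes, 15 miRNAs passed as higher and 108 as lower. For the others of the 26, dim arrays and the change from D10 to D12 cannot be told apart here, since 3 brighter D10 arrays leave few samples. A biological difference between the days stays open and untested.

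Second, far more miRNAs were called higher than lower on D20 against D16. The choice of scaling may account for the split: the share higher was 84.2% as reported, 46.4% with the authors' values and 49.6% with the percentile over all probes, though 81.4% of 43 with normexp. For single miRNAs scaling stays open, since 55 of the 117 called higher were called higher under the percentile over all probes, quantile normalization and the authors' values as well. Brighter D20 arrays are argued against as the cause for these miRNAs by the pairs of arrays on the same slide in which the D20 array was no brighter at the scaling percentile. There were 3 such pairs, on slides 2 and 4, and they involved only 2 D20 arrays, replicates 2 and 4. At that percentile, which also divides the values, the D20 arrays lay at 1468.9 against 1671.1 and 1562.2, and at 1669.7 against 1740.5. A lower divisor on D20 by itself raises the differences. The median over the 117 of the mean difference in the pairs was 1.639, against 1.595 over all arrays. On the 20 positive control probes with signal on all arrays, the D20 array differed from its D16 partner by a median of -0.22, -0.11 and -0.19 log2. Its percentile over all probes was higher, at 11.19 against 5.411 and 6.923 and at 15.21 against 6.708. That measure lies near background and may itself rise with the miRNAs at issue, which was not tested. The 117 were chosen with these arrays among others. Of the 98 miRNAs called higher from the 3 D20 and 2 D16 arrays outside the pairs, 96 were higher within the pairs, with a median of 1.71. The day and the dissected tissue, which change together, stay open as biological explanations.

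Last, all 6 mesenchymal, 5 of 7 endothelial (with 2 lower) and 3 of 4 erythroid miRNAs were higher on D20 than on D16. Blood and a change within the trophoblast cannot be told apart for the erythroid list, with a median of 2.574, because the labels give no D20 sample without blood, nor for the mesenchymal list, where the earlier arrays disagree. ssc-miR-451 lay between 0.483 and 2.609 on all D20 arrays, and within that range on D10 replicate 1 (1.906) and D12 replicate 1 (0.548), where no mesenchymal miRNA was detected. hsa-miR-144, its cluster mate, was below background on that D10 array. On the earlier arrays with both detected, mesenchymal miRNAs were compared with the level their D20 proportion to ssc-miR-451 gives. Only members for which this level lay above the array's detection limit counted. The median difference was -2.81 over 5 members on D12 replicate 1. On D16 replicates 3 and 4 it was -0.602 and 0.03, over 2 members each. The median over these arrays was -0.602. On the D16 arrays ssc-miR-199a* was expected at only -4.976 and -5.661, with the floor at -6.853. The D16 values thus rest on few, dim members and the large shortfall on 1 array, so blood stays undecided for this list. The day and the tissue part dissected may account for these changes, and neither was tested.

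Other divisions of the same arrays into groups of the same sizes were tried, 100 for each comparison with the real one included, without regard to slide. For D11 against D10, 14 gave at least as many miRNAs as the real count of 1, and the highest other gave 45, so chance cannot be excluded. For D12 against D11, 2 gave at least 11, with 21 the highest other, and for D12 against D10, 2 gave at least 40, with 62 the highest other. Within slides, 2 of 20 divisions (share 0.1) and 2 of 36 (share 0.0556) gave as many, and with slide as a block 1 of 20 and 3 of 36 did, so chance is not excluded for either. The division with 62 set D12 replicates 2 and 5 and 3 dim D10 arrays against the rest, and without the dim D10 arrays the real count was 8. For D16 against D12, D20 against D16 and the F test, 1 division each, the real one, reached 54, 139 and 192, against 19, 84 and 77 for the highest other. This is the smallest share that 100 divisions can give, so chance is unlikely but not excluded for divisions that ignore slide. Within slides the real division was also alone for D20 against D16 (1 of 36, share 0.0278, with 88 the highest other), again the smallest share possible. D16 against D12 had only 4 divisions within slides, and the F test was not divided so.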
